A study of Mus musculus with 7 samples.

How the data were processed

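EdU-seq was carried out on granule cell progenitors (GCPs), the dividing precursors of cerebellar granule neurons, taken from mouse cerebellum at postnatal day 7. Per the labels' protocols, the cells were cultured for 24 h with vehicle (Control), with Sonic hedgehog (Shh), or with Shh and 1 µM PHA767491, an inhibitor of the Cdc7 kinase (Cdc7i) that was present for the last 4 h. The thymidine analogue EdU was given at 100 µM for 15 min, coupled to biotin, and the sheared DNA that carried it was captured on streptavidin. The 7 samples came from 2 separate experiments, named LT530 and LT531 in the labels. Each experiment had a Control, a Shh and an input sample of biotinylated DNA before capture, and LT531 had the only Shh plus Cdc7i sample. The 2 inputs entered only as the background of the peak calls, so 5 peak lists were analysed. As the labels state only that 2 experiments were done, p-values between groups measure only the spread between these samples.

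Reads were aligned to the mm10 mouse genome with Bowtie 2.3.1, per the labels' protocols, and the submitters' processing notes name Bowtie2. Peaks were called with MACS2 2.1.1.20160309 in its broad, paired-end mode, once per captured library and not on pooled libraries, per the file headers. The headers give a q-value threshold of 0.05, an effective genome size of 1.87e+09, 1 fragment kept per position, and the input of the same experiment as background over 1000 and 10000 bp. They also state that the larger of library and input was scaled down to the smaller, by factors of 0.484, 0.493 and 0.478 for LT530 Shh, LT531 Shh and LT531 Shh plus Cdc7i, and not at all for the Control libraries. The deposited lists give, for each peak, its start, end and length in bp as 1-based positions and a pileup signal in fragments after the authors' scaling. They also give the authors' −log10 p-value and −log10 q-value, and the authors' fold enrichment, the ratio of pileup to the local background from the input. Fold enrichment is the authors' own value per peak and served to describe, rank, filter or stratify peaks within a list. The exceptions were the order of named peaks, which sums the values of 2 lists, and an alternative that keeps peaks at or above the median of all lists. The lists were scaled differently, so that alternative is not an equal threshold for each.

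The depth of each library was read from the file headers. Before filtering, the libraries held 24216412 (LT530 Control), 53086317 (LT530 Shh), 13289235 (LT531 Control), 54676590 (LT531 Shh) and 49824405 fragments (LT531 Shh plus Cdc7i). After repeated fragments at a position were dropped, 8182304, 21810250, 5287838, 20048815 and 20692649 were left in the same order, and the redundant share was 66%, 59%, 60%, 63% and 58%. The inputs kept 10558214 (LT530) and 9888231 fragments (LT531). The fragment length in the headers was 173 and 167 bp in the Control libraries, 108 and 96 bp in the Shh libraries and 104 bp with Cdc7i, so that depth and fragment length both went with the group.

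Peaks on chromosomes 1 to 19, X and Y were analysed, and peaks on the mitochondrial genome and on unplaced sequence were counted apart. The genome was the GRCm38 patch 6 reference, which shares the mm10 coordinates of these chromosomes, with GENCODE M21 genes. Peaks overlapped if they shared at least 1 bp. Overlaps and gene positions were compared with 10000 random placements of the peaks, each within its own chromosome and outside assembly gaps, and GC content with 1000 placements. These permutation tests compare peak positions within libraries, without matching repeat content, and peaks are not replicates. The smallest p they can give is 0.0001 one-sided (overlaps), 0.0002 two-sided (gene positions and gene lists) and 0.002 for GC content. Control and Shh libraries were compared by a two-sided exact permutation of the 4 libraries, whose smallest p is 0.33. Shares have exact Clopper-Pearson intervals of 95%, which cover counting error only. Peaks shared or not between lists were compared by two-sided Fisher's exact tests, which treat peaks as independent although they cluster. Those p-values are therefore too small. Families of tests were adjusted by the Benjamini-Hochberg method.

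The 14 gene lists were written before the data were examined, as were the sample groups, the tests and 61 of the 94 alternative computations. The lists were Shh pathway and targets, granule cell progenitor, differentiating granule neuron, origin licensing and firing, replication checkpoint and repair, long genes with many at common fragile sites, astrocyte and Bergmann glia, oligodendrocyte lineage, Purkinje cell and interneuron, microglia with endothelium and mesenchyme, housekeeping, replication-dependent histone, olfactory and vomeronasal receptor, and keratin. For each list and library, the number of genes whose body overlapped a peak was compared with 10000 random lists matched in 20 bins of gene length, giving 70 two-sided tests. A transcription start site (TSS) counted as near within 5 kb.

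The rule for named peaks was also fixed in advance. Peaks of both Shh lists that overlapped each other and no Control peak were ordered by the sum of the authors' 2 fold enrichments, and the 20 highest were named. So were the 10 highest peaks found in both Control lists, and the 10 highest LT531 Shh peaks without and with an overlapping Shh plus Cdc7i peak among those also found in LT530 Shh. A peak took the name of the protein-coding gene it overlapped, or of the nearest TSS within 50 kb, and otherwise its position. Members of the gene lists with a peak in at least 2 libraries could be named too. The peaks of 1 long gene are not reported here by name.

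After the peak sequences had been seen, each peak was put into 1 of 4 classes. A TA-run peak held an uninterrupted (TA)n or (AT)n run of 20 bp or more. Another tandem repeat was a 90 bp window that matched itself at 85% or more after a shift of up to 60 bp. The next class was at least 50% soft-masked or had a middle 31-mer found more than once in the genome, and the last was unmasked single copy. Matches of peaks to mitochondrial DNA and to Cdh2 mRNA were sought with blastn 2.17.0 at an e-value of 1e-10, 60 bp and 85% identity.

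Computations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, pysam 0.24.0 and matplotlib 3.10.9. The overlap, gene list and repeat steps were tested on simulated data. All 300 planted overlaps were found and 6 of 100 pairs of independent lists gave p of 0.05 or less. Of 100 random gene lists, 3 did, and 100 of 100 did with added hits. With hits drawn by length alone, 33 of 100 lists of 20 very long genes passed at 0.05 under the 20 length bins, and 2 of 100 when each gene was replaced by 1 of the 20 genes nearest in length. The latter matching was an added alternative for the long genes. All 500 planted TA runs and all 500 planted tandem repeats were called, and 0 of 500 random sequences were in either case.

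The LT number pairs the samples, since the labels tie each Control and Shh library to the same experiment and input. As a check of the pairing, the LT531 minus LT530 deviations of Control and Shh peak counts were correlated over 2732 bins of 1 Mb, with r = 0.0631. With the LT number as a replicate block, the log2 ratio of Shh over Control was 2.28 for peak number (exact permutation p = 0.5) and 1.64 for covered length (exact permutation p = 0.5).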

Results

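EdU-seq is meant to capture the DNA made during a short pulse of a thymidine analogue. A peak is a place where captured DNA exceeded the local background taken from the input. Whether each peak reflects newly made DNA was not tested. The experiment asked how Shh, the mitogen of GCPs, and an inhibitor of Cdc7, the kinase that activates licensed replication origins, changed that pattern. There were 2 Control, 2 Shh and 1 Shh plus Cdc7i libraries, from experiments LT530 and LT531. On chromosomes 1 to 19, X and Y, the lists held 294 (LT530 Control), 1075 (LT530 Shh), 321 (LT531 Control), 2081 (LT531 Shh) and 879 peaks (LT531 Shh plus Cdc7i). Median peak length was 283, 204, 315, 174 and 239 bp in that order, and the median of the authors' fold enrichment was 4.76, 4.37, 5.14, 4.46 and 4.39. The Control libraries had 8182304 (LT530) and 5287838 (LT531) filtered fragments, against 20048815 to 21810250 in the other 3.

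Shh-treated GCPs gave more EdU-seq peaks than vehicle-treated GCPs in both experiments. The Shh lists held 1578 ± 711 peaks and the Control lists 307.5 ± 19.1 (SD, n = 2 each), a 5.13-fold ratio of means. The ratio was 3.66 within LT530 and 6.48 within LT531. Peaks covered 536133 ± 178482 bp with Shh and 167098 ± 4085 bp in Control (SD, n = 2 each), a 3.21-fold ratio, with 2.50 in LT530 and 3.90 in LT531. By number, every sequence class held more peaks with Shh in both experiments. Unmasked single-copy peaks numbered 66 against 14 in LT530 and 77 against 14 in LT531, and the ratios for TA-run peaks were 2.83 and 3.48. Per 1000000 filtered fragments, single-copy peaks were 3.03 with Shh against 1.71 in LT530 and 3.84 against 2.65 in LT531, and TA-run peaks 3.90 against 3.67 in LT530 and, in the other direction, 20.3 against 22.1 in LT531. The exact permutation p was 0.33 for peak number and for covered length (n = 2 each), the smallest p this design allows. The Shh libraries were deeper and had shorter fragments. They were scaled down to the input before calling, so division by all their filtered fragments can correct for depth too much. Per 1000000 filtered fragments, the number was 76.5 ± 38.5 against 48.3 ± 17.5 (SD, n = 2 each), a 1.58-fold ratio with an exact permutation p of 0.667, and covered length scaled likewise had a log2 ratio of −0.0107. With peaks closer than 10 kb merged, the log2 ratio of covered length was 2.43, against 1.68 as called. At a common lowest pileup per fragment, a setting chosen after seeing the data, the log2 ratio of peak number was 2.24, with ratios of 5.26 in LT530 and 4.48 in LT531. That setting only filters peaks already called, so it does not equalise what each library could call.

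**Figure D1:**
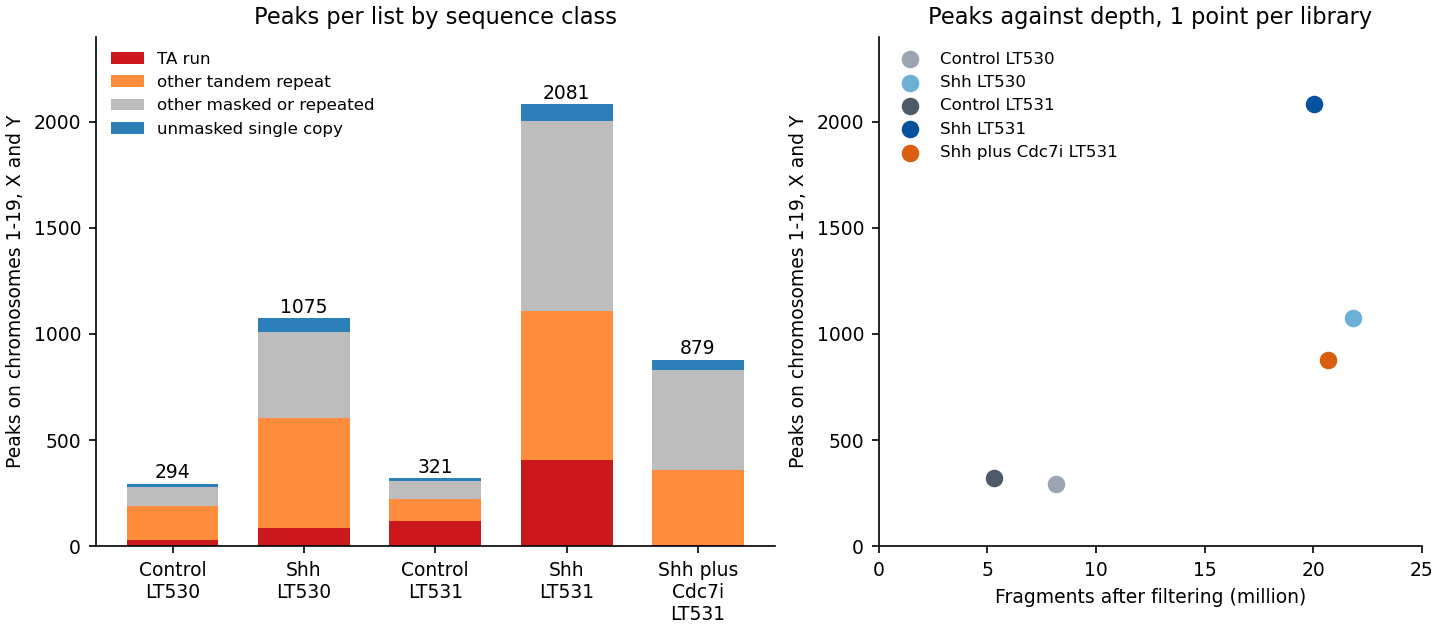
Left, stacked bars of the number of peaks in each of the 5 lists by sequence class, with totals from 294 to 2081. Right, number of peaks against filtered fragments with 1 point per library, where the 3 libraries at 20048815 to 21810250 fragments hold 1075, 2081 and 879 peaks.

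Part of the sites gave peaks in both experiments and with and without Shh, at a larger share of the shorter lists than of the longer ones. Of the LT530 Shh peaks, 535 of 1075 (49.8%, interval 46.7 to 52.8) overlapped an LT531 Shh peak, and 90 of 321 LT531 Control peaks (28.0%, 23.2 to 33.3) overlapped an LT530 Control peak. Of the LT531 Shh peaks, 25.1% overlapped an LT530 Shh peak. In LT530, 145 of 294 Control peaks (49.3%, 43.5 to 55.2) overlapped a Shh peak, and in LT531 211 of 321 did (65.7%, 60.3 to 70.9). In turn, 13.5% of LT530 Shh peaks and 10.4% of LT531 Shh peaks overlapped a Control peak of the same experiment. Across experiments, where the input was not shared, 152 of 294 LT530 Control peaks (51.7%) overlapped an LT531 Shh peak and 139 of 321 LT531 Control peaks (43.3%) an LT530 Shh peak. Random placement gave a mean of at most 0.632 overlapping peaks in any of these pairs, with a permutation p of 0.0001 each. The placements did not match repeat content, and peaks lay mostly in masked sequence. Lists rich in the same repeats could pass as well, so these p-values cannot tell shared sites of DNA synthesis from shared repeats. A total of 61 LT531 Shh peaks overlapped a peak in all 4 other lists.

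A set of 339 LT531 Shh peaks was found in LT530 Shh and in neither Control list. Its 20 highest peaks all held a TA run, of 45 to 163 bp. The highest lay on chromosome 1 at 49018286 to 49018418, with no protein-coding TSS within 50 kb and a fold enrichment of 70.7 in LT531 and 5.96 in LT530. Introns of 4 genes carried such a peak. They were Grik4, a kainate receptor subunit (chromosome 9, 42725390 to 42725525, fold 24.5 in LT531), Zbbx (chromosome 3, 75135246 to 75135402, fold 18.5), the zinc finger gene Zfp558 (chromosome 9, 18460268 to 18460430, fold 17.5) and Aoah, an acyloxyacyl hydrolase (chromosome 13, 20974933 to 20975077, fold 16.7). Their folds in LT530 Shh were 5.25, 3.71, 4.35 and 7.58 in the same order, against a median of 4.37 in that list. The LT531 fold was thus the larger part of each sum. The Zfp558 peak was a TA run over its whole 163 bp. The Grik4 peak began with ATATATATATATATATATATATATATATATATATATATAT at 42725390 to 42725429. A further 2 peaks had a nearest TSS, that of Lmod2, a muscle leiomodin, at 15907 bp and that of Gm6121 at 34555 bp, and 14 had none within 50 kb. The middle 31-mer of the Zfp558 peak has 354720 copies in the genome, and that of the chromosome 1 peak 4326. Those of the Lmod2 and Gm6121 peaks have 2993 each, and those of Grik4, Aoah and Zbbx 1, 1 and 2. The position and gene of a peak with many copies, here and below, are therefore uncertain.

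The 10 highest of the 90 peaks found in both Control lists were in both Shh lists too, and 7 of them held a TA run of 50 to 63 bp. They included introns of Tgfbr1, a TGF-beta receptor (chromosome 4, 47390563 to 47390967, fold 32.4 in LT531 Control), Mgat4c, a glycosyltransferase (chromosome 10, 101787168 to 101787659, fold 29.03), and Gpc5, a glypican (chromosome 14, 116367858 to 116368181, fold 21.2). The highest, on chromosome 12 at 97061431 to 97061790, held no TA run and matched mitochondrial DNA. Its fold was 98.7, 78.2, 105, 59.1 and 54.3 in LT530 Control, LT530 Shh, LT531 Control, LT531 Shh and LT531 Shh plus Cdc7i. Its middle, at 97061592 to 97061631, reads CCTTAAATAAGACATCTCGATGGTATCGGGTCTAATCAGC. A second mitochondrial-like peak, on chromosome 6 at 9889949 to 9890152, was also in all 5 lists. These matches were sought after the peaks had been seen.

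Peaks lay mostly in repeated sequence. Masked sequence made up at least 50% of the peak for 74.5%, 70.1%, 76.6%, 71.5% and 63.1% of peaks in LT530 Control, LT530 Shh, LT531 Control, LT531 Shh and LT531 Shh plus Cdc7i, against 28.3% to 31.2% at random. TA runs, a class chosen after the values were seen, were in 30 of 294 LT530 Control peaks (10.2%, 6.99 to 14.3), 85 of 1075 LT530 Shh peaks (7.91%, 6.36 to 9.68), 117 of 321 LT531 Control peaks (36.5%, 31.2 to 41.98) and 407 of 2081 LT531 Shh peaks (19.6%, 17.9 to 21.3), against 0.227% to 0.727% at random. With Cdc7i they were in 7 of 879 (0.796%, 0.321 to 1.63), against 0.493% at random. In LT531, where the TA share was lower in the Shh library than in the Control library, the other classes had Shh over Control ratios of 5.50 to 10.3, against 3.48 for TA-run peaks. Among the 100 highest peaks by fold, TA runs were in 23, 35, 87, 89 and 5 in the same order of lists.

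Longer TA runs carried peaks more often in LT531 Shh. Of 14655 runs of 20 to 29 bp in the genome, 0.594% (0.476 to 0.732) had a peak, and of 6054 runs of 50 bp or more, 3.72% (3.25 to 4.22). Runs that share a peak were each counted, so these intervals are too narrow. The shares of the longest runs were 1.44% in LT531 Control, 1.26% in LT530 Shh, 0.479% in LT530 Control and 0.0991% with Cdc7i. Median GC content was above random placement in LT530 Control (47.2%, difference 5.74 points), LT530 Shh (48.4%, 6.64), LT531 Shh (46.8%, 5.14) and LT531 Shh plus Cdc7i (49.2%, 7.42), each with a permutation p of 0.002. It was below in LT531 Control (38.0%, difference −3.53, permutation p = 0.002), and 4.15 points above once TA-run peaks were left out.

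**Figure D2:**
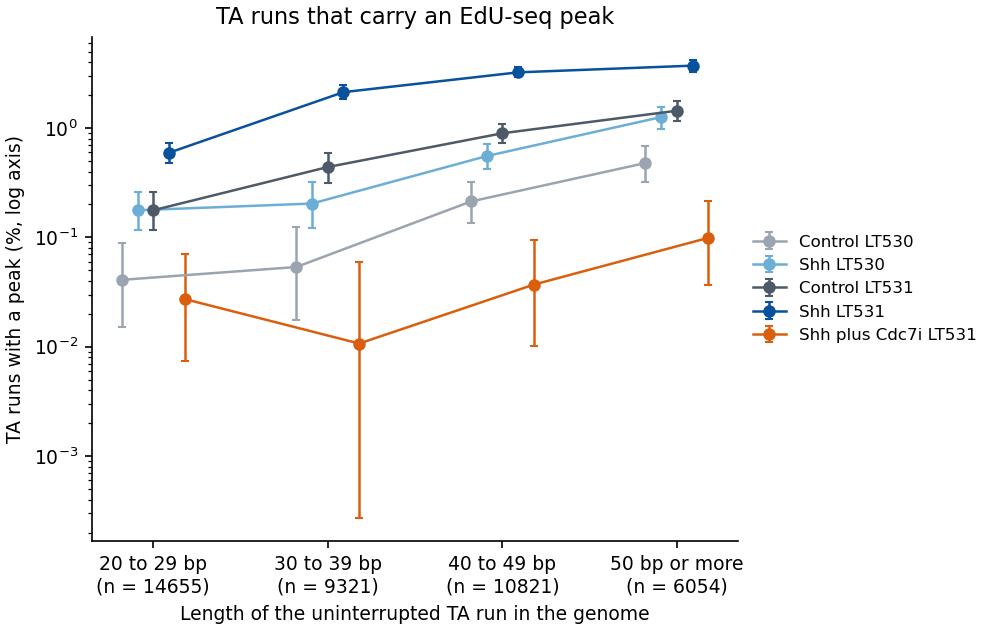
Share of the genome's TA runs that overlap a peak (percent, log axis) by run length, for each library, with exact 95% intervals as bars. In LT531 Shh the share went from 0.594% at 20 to 29 bp to 3.72% at 50 bp or more, and with Cdc7i it was 0.0273% and 0.0991%.

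Cdh2, the gene of the adhesion protein N-cadherin (chromosome 18, 16588877 to 16809246, minus strand), held 14 peaks in LT531 Shh and 0 in each of the other 4 lists. It was singled out after its values were seen. All 14 lay on exons, which make up 3.66% of the gene, against 0.723 at random (permutation p = 0.0001), and they touched 15 of its 17 exons. Their fold enrichment ran from 9.22 to 42.0 with a median of 21.5. They covered 2592 of 2718 coding bp (95.4%), 0 of 2125 untranslated bp and 0.219% of the introns. A peak on chromosome 4 at 87103431 to 87103789, with a fold of 33.2 in the same list, matched Cdh2 mRNA.

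**Figure D3:**
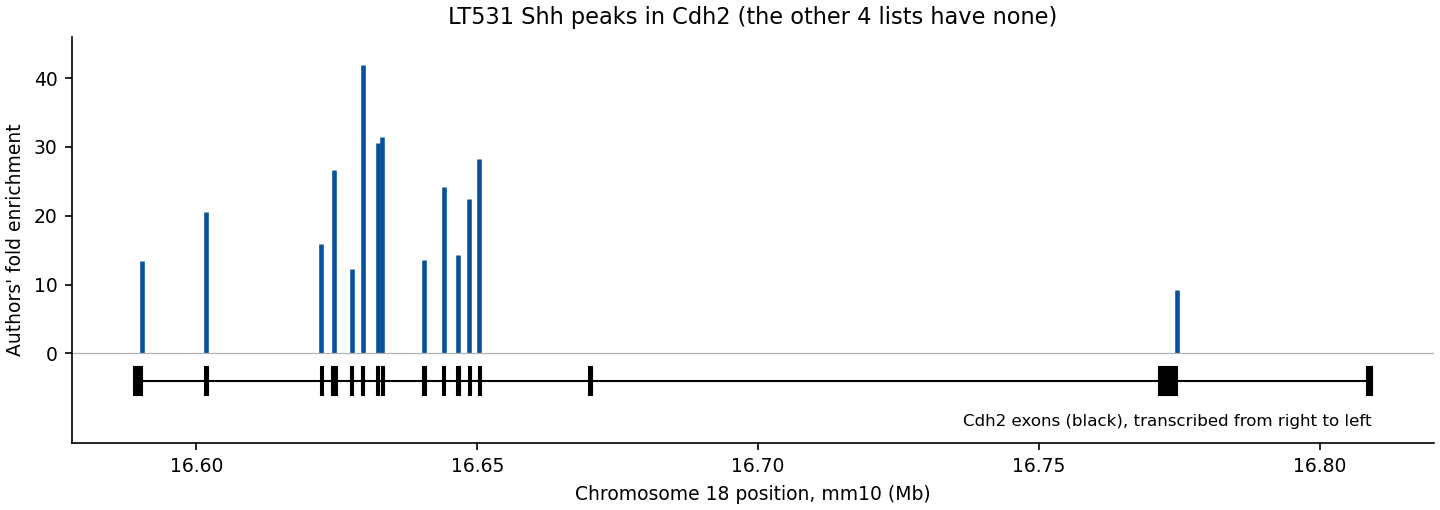
The authors' fold enrichment of the 14 LT531 Shh peaks (blue bars) by position along Cdh2 on chromosome 18 in Mb, above its exons (black). Every bar stands on an exon, and the highest reaches 42.0.

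Peaks were rarer inside protein-coding genes than random placement gave in 4 of the 5 lists, and in the same direction short of the threshold in LT530 Control. Gene bodies held 36.2% of LT530 Shh peaks against 40.6% at random (adjusted permutation p = 0.0115), and 35.2% of LT531 Shh peaks against 40.2% (adjusted p = 0.0006). The share was 28.97% against 39.8% in LT531 Control and 31.6% against 40.3% with Cdc7i (adjusted permutation p = 0.0006 each), and 33.7% against 39.3% in LT530 Control (adjusted permutation p = 0.0737). Exons held 2.51% of LT530 Shh peaks against 6.26% and 2.93% of LT531 Shh peaks against 5.87% (adjusted permutation p = 0.0006 each). The exon share did not pass in LT530 Control (3.401% against 6.57%, adjusted permutation p = 0.0502), LT531 Control (4.98% against 6.77%, adjusted permutation p = 0.317) or with Cdc7i (4.66% against 6.55%, adjusted permutation p = 0.0502). A TSS lay within 5 kb of 7.26% and 6.82% of the Shh peaks, against 7.96% and 7.83% (adjusted permutation p = 0.502 and 0.135). With placement matched for GC content the TSS share was below random, by a log2 ratio of −0.48 in LT530 and −0.46 in LT531. With all annotated genes in place of protein-coding genes it was above random, by 0.22 and 0.13, and the gene body share of LT530 Shh no longer passed. In all, 102, 341, 94, 590 and 233 of 21911 protein-coding genes held a peak in LT530 Control, LT530 Shh, LT531 Control, LT531 Shh and LT531 Shh plus Cdc7i.

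The long genes, many of which lie at common fragile sites, were the only list of the 14 with an adjusted call. In LT531 Shh, 12 of the 21 held a peak against 4.12 at random (permutation p = 0.0002, adjusted p = 0.014). They included Immp2l, Nrg3, Magi2, Auts2 and Cntnap2, which held a peak in at least 2 libraries. LT530 Shh had 4 (2.15 at random), LT530 Control 0, LT531 Control 2 and Shh plus Cdc7i 5 (1.47 at random, permutation p = 0.0272, adjusted p = 0.635). The call ended when each gene was matched to genes nearest in length, at 12 against 8.41 (permutation p = 0.165), and without TA-run peaks, at 9 against 3.25 (adjusted p = 0.173). In introns of Immp2l, a mitochondrial peptidase gene (chromosome 12, 41777921 to 41778094 in LT531 Shh), and of Magi2, a synaptic scaffold gene (chromosome 5, 20443484 to 20443606), the same site had a peak in both Shh lists and with Cdc7i. Auts2, a neurodevelopmental gene, had an intronic TA-run peak (chromosome 5, 132379477 to 132379647) with a fold of 26.7 in LT531 Shh, 25.7 in LT531 Control, 7.52 in LT530 Shh and 6.19 with Cdc7i.

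Other lists had few genes with a peak and no adjusted call, and 3 of the 70 tests had an unadjusted p under 0.05. Of 17 genes of the Shh pathway, only Smo, which transduces the Shh signal, held a peak, in an intronic tandem repeat (chromosome 6, 29747935 to 29748914 over the 5 lists) with a fold of 2.15 to 2.98. Of 34 origin genes, only Orc5, a subunit of the origin recognition complex, did, in introns in both Shh lists and with Cdc7i. The Orc5 peaks of these lists did not overlap one another. Random means for the origin genes were 0.413 (LT530 Shh), 0.697 (LT531 Shh) and 0.246 (with Cdc7i). Of 11 Purkinje cell and interneuron genes, Car8 had a peak in LT530 Shh and, at another site, with Cdc7i, and Itpr1 had one in LT531 Shh. Of 15 genes of differentiating granule neurons, Cadps2 had one with Cdc7i. Itpr1 and Cadps2 are named after their values were seen. Olfactory and vomeronasal receptors, 1418 genes, had 0, 0, 2, 3 and 1 in LT530 Control, LT530 Shh, LT531 Control, LT531 Shh and Shh plus Cdc7i, and the 0 in LT530 Shh was set against 5.52 at random (permutation p = 0.0056, adjusted p = 0.196). A count of 0 in every list was found for the granule cell progenitor genes (12), checkpoint and repair (22), astrocyte and Bergmann glia (10), oligodendrocyte lineage (9), microglia with endothelium and mesenchyme (13), housekeeping (12), histone (66) and keratin genes (110), where the random means were all under 1. Peaks within 5 kb of a TSS gave 0 adjusted calls and 0 tests with an unadjusted permutation p under 0.05.

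Within LT531, the Shh plus Cdc7i library held fewer peaks than the Shh library, at a similar depth and against the same input. The ratio was 0.422 (interval 0.390 to 0.457, counting error only), and 0.569 for covered length. TA runs stood apart from the other classes, with 407 peaks in Shh and 7 with Cdc7i, a 58.1-fold ratio (28.0 to 146). Other tandem repeats had a ratio of 2.003, other masked or repeated sequence 1.90, and unmasked single-copy sequence 1.51. With the LT530 Shh list in place of the LT531 Shh list these were 12.1, 1.47, 0.866 and 1.29 in the same order, so for other masked or repeated sequence (407 against 470 peaks) the direction turned. The condition had 1 library, so each comparison with it is between libraries, not conditions. The LT530 Shh list, with 1075 peaks, held 1.22 times as many peaks as the Cdc7i list, and the LT531 Shh list 1.94 times as many as LT530 Shh.

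Of the LT531 Shh peaks, 473 of 2081 (22.7%, 20.9 to 24.6) overlapped a peak with Cdc7i (permutation p = 0.0001), and 14.05% did among peaks with a fold at or above the median of all lists, or 15.1% with each list's own median. The share was 8 of 407 for TA-run peaks (1.97%, 0.852 to 3.84) and 465 of 1674 for all other peaks (27.8%, 25.64 to 29.99). Of the TA-run peaks, 21.4% were also in LT530 Shh and 26.3% in LT531 Control. Peaks shared with LT531 Control overlapped a Cdc7i peak more often, at 93 of 216 (43.1%, 36.4 to 49.95), than peaks absent from it, at 380 of 1865 (20.4%, 18.6 to 22.3), with an odds ratio of 2.95 (Fisher's exact p = 2.08e-12). The odds ratio was 1.57 among peaks at or above the median fold of all lists (Fisher's exact p = 0.0664), 1.28 at or above each list's own median (Fisher's exact p = 0.336), 5.73 with peaks extended by 10 kb (Fisher's exact p = 9.95e-49) and 12.4 without TA-run peaks (Fisher's exact p = 1.14e-31). These 3 lists share an input, and with sharing taken from LT530 Control, called against the other input, it was 8.17 (Fisher's exact p = 1.24e-33), and 5.62 for LT530 Shh peaks (Fisher's exact p = 1.72e-20); these, the own medians and the setting without TA-run peaks were chosen after seeing the data. Peaks also found in LT530 Shh overlapped a Cdc7i peak in 290 of 523 cases (55.4%), and the others in 183 of 1558 (11.7%). Fisher's exact tests treat peaks as independent, and peaks cluster, so the p-values given here are too small.

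The 233 LT531 Shh peaks found in LT530 Shh and absent with Cdc7i were led by TA runs, in all 10 of the highest, with runs of 45 to 62 bp. The intronic Grik4 peak was among them, and the nearest TSS was that of Lmod2, Gm10591 or Gm13304 for a further 3. Their fold in LT531 Shh ran from 23.8 to 30.5. The 10 highest of the 290 kept with Cdc7i included 8 with a TA run of 49 to 64 bp. The highest of all was the chromosome 1 peak at 49018286 to 49018418, which also led the peaks found in both Shh lists and no Control list. A further 3 TA-run peaks without a protein-coding TSS within 50 kb lay on chromosome 4 (29057362 to 29057842, fold 33.7), the X chromosome (119579198 to 119579654, fold 29.8) and chromosome 7 (93957740 to 93957889, fold 24.2). The others lay in introns of Tgfbr1 (fold 47.6 in LT531 Shh), Mgat4c (36.5), Auts2 (26.7) and Ptprd, a receptor tyrosine phosphatase (chromosome 4, 77075107 to 77075456, fold 23.0), and at the 2 mitochondrial-like sites.

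**Figure D4:**
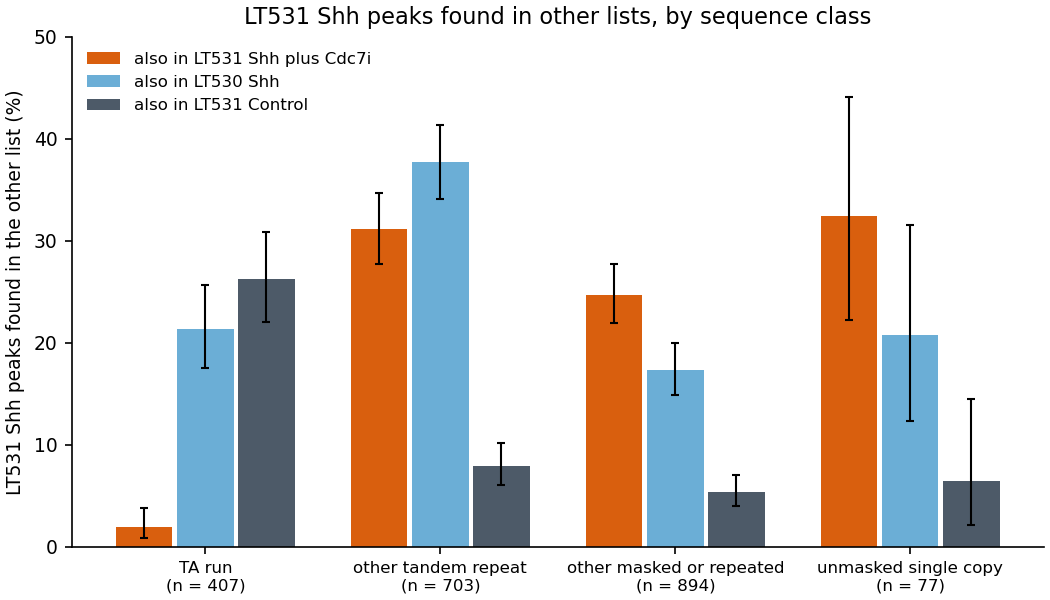
Share of LT531 Shh peaks (percent) found in LT531 Shh plus Cdc7i, LT530 Shh and LT531 Control, by sequence class, with exact 95% intervals as bars. For TA-run peaks the shares were 1.97%, 21.4% and 26.3%, and for unmasked single-copy peaks the share found with Cdc7i was 32.5%.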

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

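The depth tests of the TA-run peaks and of the Shh peak number, the common lowest pileup, and the tests of Cdh2 were chosen only after the result was seen. Outside the chromosomes analysed, the mitochondrial genome and unplaced sequence held a mean of 83.5 peaks in the Shh lists and 26.5 in the Control lists, a ratio of 3.15 (2.57 in LT530 and 3.91 in LT531), and 82 with Cdc7i. Per 1000000 filtered fragments these were 3.53 (LT530 Shh) against 3.67 (LT530 Control), 4.49 (LT531 Shh) against 4.35 (LT531 Control) and 3.96 with Cdc7i. Scaled in this way the Shh and Control lists were alike. The Shh libraries had been scaled down to the input before calling, so this division can correct too much. As depth went with the group, it cannot be told apart from the treatment as the reason for the unscaled ratio.

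TA-run peaks numbered 407 in LT531 Shh and 7 in LT531 Shh plus Cdc7i. Sequencing depth is argued against, since the LT531 Control library, the shallowest, held 16.7 times as many TA-run peaks as the Cdc7i library (7.86 to 42.5). Low GC content in general is also argued against. Among windows of at most 10% GC, those with a TA run carried an LT531 Shh peak far more often than those without (11 of 42 and 0 of 295 windows). With a Haldane correction for the count of 0, the odds ratio was 216 (12.4 to 3750). A loss of AT-rich fragments from the Cdc7i library alone cannot be told apart from an effect of the inhibitor, as peaks under 35% GC without a TA run were kept with an odds ratio of 0.679 (0.396 to 1.16) against the others, an interval too wide to decide. A dependence of TA-run signal on Cdc7 activity remains a hypothesis from 1 library, and the different TA shares of the 2 Control lists show that this class also varied between experiments.

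Cdh2 held 14 peaks in LT531 Shh and 0 in the other 4 lists. A candidate explanation is N-cadherin cDNA in that library, since 100% of the peaks lay on exons against 5.16% at random. A retrocopy in the genome of these mice is argued against by the count of 0 Cdh2 peaks with Cdc7i, made in the same experiment against the same input at a similar depth. Replication starting within Cdh2, the biological explanation tested, would need peaks in introns, and the upper bound of the share wholly in introns was 23.2%.

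More peaks were called in both Shh libraries than in the Control libraries. By number this was not confined to the masked and repeated classes, since unmasked single-copy peaks also numbered more with Shh. That class rests on reference masking and the copies of the middle 31-mer. Over all lists, 30 of its peaks lay in a dense chromosome 11 region, so it is not shown to be free of repeats. The single-copy ratio was 4.71 (2.62 to 9.09, not scaled for depth) in the experiment with the lower ratio. Per 1000000 fragments the difference was smaller, at 3.03 against 1.71 in LT530 and 3.84 against 2.65 in LT531. No interval was computed for these scaled values, and they leave out the scaling of the Shh libraries before calling. They cannot decide, so depth stays open as the reason for the single-copy excess. Sequencing depth cannot be told apart from the treatment, because both Shh libraries were deeper than both Control libraries. The log2 ratio of 2.24 at a common lowest pileup per fragment cannot decide, as that setting only filters peaks already called. Sites too weak to be called in the shallower Control libraries stay missing from it. The Cdc7i library offers no way out, as LT530 Shh exceeded it only 1.22 times at a similar depth, less than the 1.94-fold gap between the Shh libraries. An effect of Shh on DNA synthesis stays open beside it.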

How the results depend on the processing

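The alternatives without TA-run peaks, with single-copy peaks only, at a common lowest pileup, without Cdh2, with genes nearest in length, at each list's own median fold and with Control from the other input were chosen after seeing the data, and make up 33 of all 94. Of the 94 alternatives over 20 results, 73 kept direction and call or stayed within their margin, 10 moved, 5 lost the call, 2 gained it and 4 reversed. The log2 ratio of Shh over Control peak number ran from 1.87 to 2.70 with each experiment left out in turn, and covered length from 1.32 to 1.962, values with no test. Per 1000000 fragments these were 0.66 and −0.0107, the latter reversed, and covered length was 2.43 with peaks closer than 10 kb merged. The Shh libraries were scaled down to the input before calling, so dividing by their unscaled fragments can correct for depth too much. The replicate block (2.28 and 1.64) says nothing about stability, as no p in this design can pass the threshold. The log2 ratio of Cdc7i over Shh peak number, −1.24, was −0.84 against the mean of both Shh libraries, −1.47 at or above the median fold, −1.49 after merging, −0.94 without TA-run peaks, −0.59 for single-copy peaks and −0.91 at a common lowest pileup. The odds ratio of being kept with Cdc7i fell to 1.57 (Fisher's exact p = 0.0664) at or above the median fold of all lists and to 1.28 (Fisher's exact p = 0.336) at each list's own median, and was 12.4 without TA-run peaks. Overlap p-values stood at their floor of 0.0001 in every setting and say nothing about stability, while the Shh peaks kept with Cdc7i ran from 14.05% at or above the median fold to 33.9% with peaks extended by 10 kb. The gene body log2 ratio of LT530 Shh was −0.0898 with all annotated genes and no longer passed. The TSS log2 ratio passed with placement matched for GC (−0.48 in LT530, −0.46 in LT531) and reversed with all annotated genes (0.22 and 0.13). Gene list calls numbered 0 by TSS and 0 without TA-run peaks. For the long genes, the log2 ratio to random was 0.51 with genes nearest in length, where closer matching raised the random mean, and 1.47 without TA-run peaks, where fewer peaks were tested. GC content of LT531 Control was 4.15 points above random without TA-run peaks, a reversal made by leaving that class out. For the others the cause was not tested. What depth limits was not tested apart from the group, which depth and fragment length both followed.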

Other observations

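The test of a link between peak strength and sharing, that of run length and that of other cDNA were set out before their results were seen, and the dense regions and the tests with LT530 Control in place of LT531 Control were chosen only after the result was seen. A small number of 1 Mb regions held many peaks. The 10 densest, ranked by peaks summed over the 5 lists so that longer lists weigh more, held 29.5% of the Cdc7i peaks (26.5 to 32.6), 17.9% of LT530 Shh peaks (15.6 to 20.3), 14.6% of LT531 Shh peaks (13.1 to 16.2), 16.5% of LT531 Control peaks (12.6 to 21.03) and 11.9% of LT530 Control peaks (8.43 to 16.2). On chromosome 8, 20006690 to 20947443, which includes the beta-defensin gene Defb33, held 29 and 60 peaks in LT530 and LT531 Shh, 12 and 7 in the Control lists and 41 with Cdc7i. On chromosome 5, 15004830 to 15715670, with the Speer4d and Speer4c genes, held 24 and 50, 7 and 11, and 52. On chromosome 6, 47651698 to 47778237, with no protein-coding gene under its peaks, held 38 and 27 with Shh, 0 in both Control lists and 38 with Cdc7i. On chromosome 11, 3100403 to 3825057 held 13 and 22 with Shh, 2 and 4 in Control and 23 with Cdc7i, and 30 of its 64 peaks were unmasked single copy. It includes Sfi1, a centrosome gene with 4, 5 and 5 exon peaks in LT530 Shh, LT531 Shh and Shh plus Cdc7i. The middle 31-mer of the peaks had a median of 14, 6 and 16 copies in the genome in the chromosome 8, 5 and 6 regions. Among the 10 regions only that on chromosome 11 had a median of 1, so peaks elsewhere lay mostly in sequence with several copies. Whether the many peaks of these regions reflect DNA synthesis or sequence copies was not tested.

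Peaks were spread unevenly over chromosomes. Chromosome 8 held 1.961 times the number its length gives in LT530 Shh (adjusted exact binomial p = 8.06e-09), 1.94 times in LT531 Shh (adjusted p = 3.72e-16) and 2.25 times with Cdc7i (adjusted p = 5.47e-12), and 1.434 and 1.248 times in LT530 and LT531 Control (adjusted exact binomial p = 0.464 and 0.809). Chromosome 5 held 1.47, 1.41 and 2.16 times (adjusted exact binomial p = 0.00293, 0.000115 and 4.52e-12) and 1.34 and 2.007 times in the Control lists (adjusted exact binomial p = 0.464 and 0.00165), and the X chromosome 0.512, 0.677 and 0.461 times (adjusted p = 0.000116, 0.000455 and 6.17e-05), with 0.771 and 0.757 in the Control lists (adjusted exact binomial p = 0.592 and 0.809). The Control lists are shorter, and a difference between lists was not tested. Peaks cluster, so these p-values, which treat peaks as independent, are too small. On chromosome 8, the dense regions starting at 20006690 and 55112429 held 29 and 17 of 100 LT530 Shh peaks (51.0 by length). They held 60 and 24 of 191 in LT531 Shh (98.7 by length) and 41 and 13 of 94 with Cdc7i (41.7). On chromosome 5, those starting at 14905566 and 15004830 held 16 and 24 of 88 peaks in LT530 Shh. In LT531 Shh they held 20 and 50 of 164, and with Cdc7i 23 and 52 of 106. The excess on these chromosomes in the Shh and Cdc7i lists thus lay in few regions.

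Peaks of LT531 Shh shared with Control were kept with Cdc7i more often than the rest. That stronger peaks are simply called in every library was tested as the reason, with fold enrichment as the only measure of strength. Within quintiles of the LT531 Shh fold enrichment the Mantel-Haenszel odds ratio was 3.58 (2.51 to 5.09, permutation p = 0.0002), and without TA-run peaks it was 6.97 (4.25 to 11.4). LT531 Shh, Control and Cdc7i were called against the same input, so a ratio above 1 could come from sites low in it. With sharing taken from LT530 Control, called against the other input, the ratio was 9.57 (6.37 to 14.4), and 5.80 (3.78 to 8.89) for LT530 Shh peaks. Neither fold enrichment nor chance gaps in the LT531 input may thus account for it alone. Pileup, q-value and peak length were not used as strata, so peak strength in those terms stays open. Sites low in both inputs stay open as a reason, and among peaks at or above each list's own median fold the odds ratio was 1.28 (Fisher's exact p = 0.336). LT531 Shh peaks also found in LT530 Shh were kept in 290 of 523 cases, and the others in 183 of 1558. Being kept was thus not particular to sharing with Control, and sites that recur in any list stay open as a reason too. The tests here treat clustered peaks as independent, so their intervals are too narrow.

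A hypothesis that longer TA runs carry peaks more often was tested in LT531 Shh, where the share was 6.26 times higher for runs of 50 bp or more than for runs of 20 to 29 bp, with intervals that do not overlap. Runs that share a peak were each counted, so those intervals are too narrow. Longer uninterrupted TA repeats may be sites where EdU-labelled DNA is recovered more often, but how reads map in such runs was not tested. A search for other cDNA besides Cdh2 in the LT531 Shh library found 0 other genes with at least 3 exon peaks there and none with Cdc7i.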
